A study of Mus musculus with 9 samples.

How the data were processed

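Total RNA from the lungs of C57BL6 mice was measured on 9 Affymetrix mouse expression arrays. The labels place them in 3 groups of 3 arrays from an asthma model induced with ovalbumin (OVA): mice challenged with saline, mice challenged with OVA, and mice challenged with OVA and given an agonist of EP3, a receptor of prostaglandin E2. Arrays are named by group and by the replicate number in their titles, 1 to 3. The labels do not say whether the 3 arrays of a group are 3 mice, and the p-values therefore measure the spread between these samples, which can be technical.

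The deposited values are intensities on a linear scale, 1 per probe set and array, with values below 0 on every array. Some signal had thus been subtracted before deposition, and what was subtracted is not given. The scanner software, the summarization algorithm, the scale constant and the array protocol are not given in the sources used here. The arrays had not been brought to a common level: the 2% trimmed mean of the deposited intensity ran from 138.7 to 241.2 between arrays, and the median from 62.9 to 104.6. Each array was multiplied by a factor between 0.741 and 1.29 to reach the mean of the 9 trimmed means. Intensities are given on that common scale, as mean ± SD of 3 arrays.

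Of 12488 probe sets, 66 controls were left out. The others carry 1 gene symbol (10833), several (396) or none (1193) in the array's probe table, and 10817 of those with 1 symbol were found by gene ID in a RefSeq gene table (GRCm38.p6, used for names only), which changed 0 symbols. Scaled intensities below 3.10, the 20th percentile of all values, were raised to that floor, and log2 was taken. A probe set was tested when at least 3 of the 9 arrays exceeded 44.7, the 40th percentile, which also serves as the detection limit. That left 7920 probe sets (63.8% of those that are not controls) for 5950 genes. Where all arrays of a group lay at or below the detection limit, and all arrays of the other group above it, the fold is given as a lower bound, the geometric mean of the brighter group over the detection limit, and written "at least". Where only some arrays of the dimmer group lay below the limit, the log2 change with all values held at the limit is given beside the other for the genes most affected. A group whose arrays all lie below the floor has no spread on the log2 scale, so the standard errors of such probe sets leave that group's spread out and their p-values come out small.

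Groups were compared with limma 3.58.1 (lmFit and eBayes, R 4.3.3) in 1 fit of the 9 arrays with 6 residual and 1.69 prior degrees of freedom. All gene p-values are two-sided limma p-values, adjusted by Benjamini-Hochberg over the 7920 probe sets, with a threshold of 0.05. Folds are 2 to the power of the log2 change. The 30 gene lists (cell type markers, pathways of the allergic response, other tissues a piece of lung can hold, clock, stress and immediate early genes) were tested with limma's camera at a preset correlation between genes of 0.01, with the brightest probe set per gene, and adjusted over the 29 lists with at least 3 tested members. Camera with an estimated correlation and fry (limma, with statmod 1.5.0) were run beside it. The counts "adjusted over the list alone" use limma p-values adjusted among a list's own members.

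The comparisons of OVA with saline and of agonist with OVA share the OVA arrays, so chance alone makes their changes run opposite. To take this out, probe sets were picked without 1 OVA array and the agonist arrays were then set against that array, for each OVA array in turn. The mean of the 3 medians was compared with all 20 labelings of the 6 challenged arrays (exact permutation). The covariance of both changes was also set against the part that shared arrays give, from the residual variance and from 100 simulations of unchanged groups.

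The tests, filters, lists, named-gene rule and alternatives were fixed before the data were examined. Named genes are, for each comparison, the 10 largest rises and 10 largest falls that passed with non-overlapping groups (1 probe set per gene, no unnamed probe sets or antigen receptor segments), up to 4 members of each list with the largest change, passing ones ahead, and Ptger1 to Ptger4. Alternatives were quantile normalization, equal array medians, no floor (log2 of the value + 1), a floor at the 40th percentile, no filter, a filter at the 60th percentile, an intensity trend with a robust prior, array weights, only the 6 arrays compared, the replicate number as a block, each array left out in turn, other thresholds (adjusted p of 0.1; at least 2-fold), the other list tests, and the mean of a gene's probe sets.

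The procedure was tested on 20 simulated sets of 7920 probe sets with the spread of these arrays, 200 of them changed. For OVA against saline, 31.4% of 1.5-fold, 60.1% of 2-fold and 86.1% of 4-fold changes were recovered, with 4.72% of calls false. For agonist against OVA the shares were 31.8%, 60.6% and 85.6%, with 4.86% false. For agonist against saline with nothing changed, 1 probe set was called in the 20 sets together. Of lists shifted by 0.5 on the log2 scale among 5950 genes, 93.3% were recovered and 0.682% of unrelated lists were called. The simulated genes were independent, whereas the estimated correlation within the real lists reached 0.34. The shares for lists therefore do not carry over to the real lists. The simulated values were also normal, were not held at the floor and held no deviating array. Of the real calls, 96 of 752 for OVA against saline had a group at or below the detection limit. For agonist against OVA 33 of 218 had one. The shares of recovered and false probe sets therefore do not carry over to the real calls either. With 3 arrays per group, the number of arrays limits the precision.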

Results

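Lung total RNA from 9 arrays was compared between 3 groups of 3: mice of an asthma model challenged with saline, mice challenged with ovalbumin (OVA, the egg-white protein that serves as the allergen), and mice challenged with OVA and given an agonist of EP3, a receptor of prostaglandin E2. The titles of both OVA groups carry a time of 24 h. The dose and timing of the agonist are not given in the sources used here. On the common scale, 59.6% to 60.6% of the probe sets of each array lay above the detection limit of 44.7, and 16.4% to 18.7% lay at or below 0. Arrays of the same group correlated with r between 0.879 and 0.926 across probe sets, which are not independent replicates. Pairs from different groups reached into that range, such as saline and agonist replicates 2 (0.9228). Agonist replicate 3 correlated at 0.88 and 0.8787 with agonist replicates 1 and 2. With OVA replicates 1, 2 and 3 it correlated at 0.8697, 0.8808 and 0.904.

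The largest axis of variation separated OVA from saline lung. Along principal component 1 (36.1% of the variance of the tested probe sets) the saline arrays lay at −21.1, −26.4 and −30.9 and the OVA arrays at 44.5, 40 and 29.6. Agonist replicates 1 and 2 lay with the saline arrays, at −24 and −22.7, and agonist replicate 3 between the groups, at 11. On component 2 (13.4%) the agonist arrays lay at −25.1, −2.94 and −33.2, the saline arrays at 9.66, 11.2 and 22.1 and the OVA arrays at 15.8, 10.7 and −8.35. Of the bacterial transcripts that are spiked into each hybridization, 2 controls were lowest on the arrays numbered 2 in every group: the bioD control read 2054 to 2833 on the arrays numbered 1, 991 to 1537 on those numbered 2 and 1708 to 2260 on those numbered 3, and the bioC control 649 to 917, 290 to 409 and 501 to 658. The bioB control (its M probe set) was not: it read 297.8, 436.6 and 229.5 on saline replicates 1, 2 and 3, 205.8, 300.9 and 189.7 on OVA and 365.1, 371.7 and 244.7 on agonist replicates. Changes within each replicate number are therefore given beside the pooled ones.

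The change from saline to OVA asks what allergen challenge altered in the lung. In OVA lung 11 of 21 genes of the type 2 immune response rose, as did 7 of 14 mucus genes, 8 of 17 chemokines and 17 of 28 markers of macrophages and dendritic cells, while 6 of 13 markers of heart muscle, 12 of 24 of endothelium and 5 of 8 of alveolar type 1 cells fell. Camera called a shift of each of these lists, 15 of 29 in all, and 0 with an estimated correlation (adjusted p between 0.158 and 0.263 for these lists). Ccl17, a chemokine that attracts type 2 helper T cells, averaged −109.8 ± 6.43 in saline and 579.6 ± 132 in OVA lung, at least 12.7-fold higher (adjusted p = 4.44e-07). Clca1, secreted by mucus-producing cells, went from 57.4 ± 8.4 to 6166 ± 756, a 108-fold rise (log2 change 6.75 ± 0.93 SE, adjusted p = 0.0115), and Mmp12, the elastase of macrophages, from 117 ± 40.4 to 2046 ± 330, 18-fold (adjusted p = 0.00263). Among the falls, Cyp2f2, a cytochrome P450 of club cells, went from 3577 ± 271 to 1834 ± 215, 1.96-fold lower (adjusted p = 0.0115).

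Of 7920 probe sets, 752 (619 genes) passed limma's test between OVA and saline, 402 higher and 350 lower, 241 of them by at least 2-fold, and 2302 had an unadjusted p under 0.05. All of the 752 had non-overlapping groups, as had 37.6% of the tested probe sets, against 10% by chance. Scaling the arrays to equal medians instead gave 435 higher and 254 lower, which moves the higher share from 53.5% to 63.1%. The count rests on which arrays enter. It was 150, 138 and 126 without saline replicates 1, 2 and 3, 80 and 103 without OVA replicates 1 and 2, and 50 with the replicate number as a block. Of the 83 calls of named probe sets, 12 passed with each of the 9 arrays left out, and 6 passed in 6 such settings but are not testable without an OVA array. With the replicate block 17 of the 83 passed: Alox15, C1qa, C1qb, Car3, Ccl17, Ccl2, Cks2, Col6a2, Fbp1, Isg15, Mad2l1, Nr1d1, Pax4, Six4, Tpm2 and both probe sets of Mmp12. Without OVA replicates 1, 2 and 3, 61, 55 and 22 of 74 were lost, without saline replicates 1, 2 and 3, 51 of 80, 54 of 80 and 52 of 81, and without agonist replicates 1, 2 and 3, 7 of 83, 22 of 82 and 1 of 83.

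**Figure D1:**
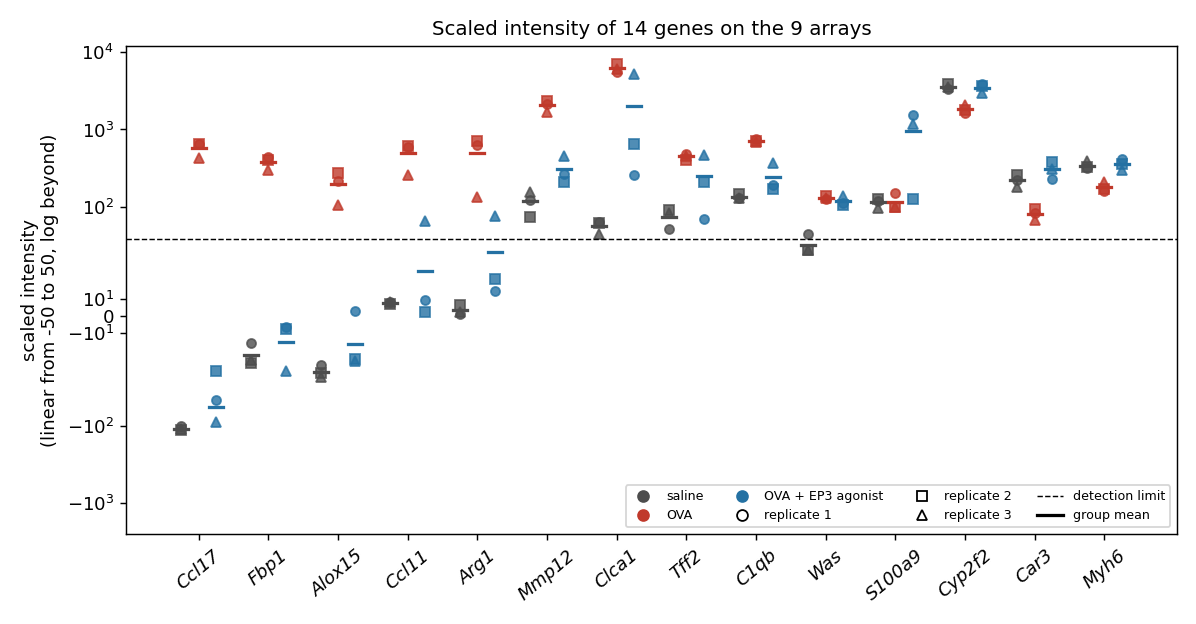
Scaled intensity of 14 genes on each of the 9 arrays (saline grey, OVA red, agonist blue; circle, square and triangle for replicates 1, 2 and 3; bars for group means), on an axis that is linear near 0 and logarithmic beyond, with the detection limit of 44.7 dashed. Ccl17, Fbp1 and Alox15 lay above the limit on the OVA arrays only, Clca1 read 257, 644.8 and 5194 on the agonist arrays, and S100a9 read 1542, 128 and 1180.5 there against group means of 115 in saline and 117 in OVA lung.

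Of 21 tested genes of the type 2 response and of alternatively activated macrophages, 11 rose in OVA lung, 0 fell and 10 did not pass. When adjusted over the list alone, 14 passed. Besides Ccl17 and Mmp12 these were led by Arg1, the arginase of alternatively activated macrophages (3.38 ± 2.54 to 494 ± 313, at least 8.83-fold, adjusted p = 0.00949), and Ccl11, the eosinophil attractant eotaxin (7.82 ± 0.629 to 493 ± 201, at least 10.3-fold, adjusted p = 0.0192). Alox15, a lipoxygenase of eosinophils and macrophages, rose at least 4.1-fold (−32.3 ± 3.72 to 197 ± 84.8, adjusted p = 0.000106). The list shifted upward (camera adjusted p = 1.23e-12; adjusted p = 0.158 with an estimated correlation), by 2.57, 2.71 and 2.21 on the log2 scale within replicate numbers 1, 2 and 3. Of 17 chemokines, 8 rose and 1 fell, with 10 passing when adjusted over the list alone. Chemokines as a list shifted upward (camera adjusted p = 2.21e-05; adjusted p = 0.158 with an estimated correlation; 2.17, 2.51 and 1.64 within replicate numbers). Ccl2, a monocyte attractant, rose at least 2.39-fold (−16.8 ± 16.2 to 117 ± 54.5, adjusted p = 0.00949). Of the eosinophil markers, only 2 were tested: Alox15, and Csf2rb2, a receptor chain for interleukin 3, at 77.7 ± 7.06 in saline and 138 ± 24 in OVA lung (adjusted p = 0.0521; 0.0181 without agonist replicate 3). Mmp12 and Arg1 passed with each array left out. Ccl17, Alox15 and Ccl2 passed without each saline and each agonist array and are not testable without an OVA array. Ccl11 lost its call without any 1 saline array and without OVA replicates 1 and 2 (adjusted p of 0.00139 to 0.0755 over the arrays left out).

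Mucus genes of goblet cells rose in OVA lung: 7 of 14 tested rose, 0 fell and 7 did not pass, with 9 passing when adjusted over the list alone. Agr2, which folds mucins, rose at least 4.96-fold (14.97 ± 8.94 to 230.1 ± 73.8, adjusted p = 0.0183), Tff2, a trefoil peptide secreted with mucus, 6.12-fold (75.04 ± 20.2 to 448 ± 37.3, adjusted p = 0.0381), and Scin, an actin-severing protein, at least 2.88-fold (12.9 ± 9.79 to 131 ± 28.9, adjusted p = 0.0348). Mucus genes as a list shifted upward (camera adjusted p = 4.05e-05; adjusted p = 0.158 with an estimated correlation), by 1.81, 1.5 and 1.47 within replicate numbers. Each of these genes lost its call without OVA replicate 1 and without OVA replicate 2, with adjusted p up to 0.0522 for Clca1, 0.0735 for Agr2, 0.0984 for Scin and 0.122 for Tff2. Agr2 also lost it without saline replicate 2, Scin and Tff2 without any saline array or OVA replicate 3, and Tff2 without agonist replicate 2.

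Of 28 markers of macrophages and dendritic cells, 17 rose, 1 fell and 10 did not pass, with 23 passing when adjusted over the list alone. The C1q chains, which macrophages secrete to start the classical complement pathway, rose most: C1qb 5.29-fold (135 ± 8.39 to 714 ± 30.9, adjusted p = 0.00854), C1qa 4.33-fold (189 ± 24.5 to 813.5 ± 45.1, adjusted p = 0.00854) and C1qc 3.87-fold (325 ± 19.9 to 1269 ± 198, adjusted p = 0.0115). Ctsk, the lysosomal protease cathepsin K, rose 2.92-fold (141 ± 41 to 402 ± 62.1, adjusted p = 0.015). Another probe set for C1qb changed by −0.43 (adjusted p = 0.268). These markers together shifted upward (camera adjusted p = 1.22e-11; adjusted p = 0.158 with an estimated correlation), by 0.81, 0.8 and 1.02 within replicate numbers. Complement and acute phase genes moved with them: 8 of 17 rose, the 3 C1q chains counted again, 0 fell, and 12 passed when adjusted over the list alone. Complement genes together shifted upward (camera adjusted p = 3.19e-05; adjusted p = 0.171 with an estimated correlation; 1.54, 1.41 and 1.01 within replicate numbers). Saa3, an acute phase protein, rose at least 31.4-fold (−33.3 ± 13.7 to 2040 ± 1540, adjusted p = 0.0239). C1qa and C1qb passed with each array left out. C1qc lost its call without OVA replicate 1 (highest adjusted p 0.0527), and Ctsk without OVA replicates 1 and 2 (0.0597). Saa3 lost it without OVA replicates 1 and 2 and without any 1 saline array (up to 0.0914).

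Interferon response genes were higher in OVA lung, 8 of 30 rising, 0 falling and 22 not passing, with 13 passing when adjusted over the list alone. Isg15, a ubiquitin-like protein that interferon induces, rose at least 1.69-fold (−30.2 ± 27.7 to 77.9 ± 22.7, adjusted p = 0.0131), Psmb9, a subunit of the immunoproteasome, 2.98-fold (75.5 ± 34.5 to 214 ± 52.5, adjusted p = 0.0348), and Ifit1, an antiviral RNA-binding protein, 2.91-fold (56.7 ± 3.39 to 165.5 ± 20.1, adjusted p = 0.0227). Interferon response genes together shifted upward (camera adjusted p = 2.43e-09; adjusted p = 0.158 with an estimated correlation), by 0.75, 0.62 and 0.89 within replicate numbers. Cell cycle genes shifted the same way, 6 of 25 rising, 0 falling and 8 passing when adjusted over the list alone. As a list they shifted upward (camera adjusted p = 0.000107; adjusted p = 0.158 with an estimated correlation; 0.33, 0.19 and 0.55 within replicate numbers). Cks2, a subunit of cyclin-dependent kinases, rose at least 1.87-fold (20.5 ± 3.73 to 84.3 ± 15.2, adjusted p = 0.00949), and Mad2l1, of the spindle checkpoint, 2.2-fold (44.7 ± 4.69 to 99.2 ± 18.5, adjusted p = 0.0136). Isg15 and Cks2 passed without each saline and each agonist array and are not testable without an OVA array. Mad2l1 lost its call without saline replicate 2 (0.0513). Ifit1 (up to 0.082) and Psmb9 (up to 0.119) lost theirs without OVA replicates 1 and 2 and without saline replicates 2 and 3. Ifit1 also lost it without saline replicate 1, and Psmb9 without OVA replicate 3 and agonist replicate 2.

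Smooth muscle genes rose as well, 4 of 11, with 0 falling and 5 passing when adjusted over the list alone. Tpm2, a tropomyosin, rose 2.43-fold (89.6 ± 8.9 to 219.8 ± 46.9, adjusted p = 0.00965) and Acta2, smooth muscle actin, 1.75-fold (1155 ± 60.5 to 2036 ± 268, adjusted p = 0.0181). The list shifted upward (camera adjusted p = 0.000166; adjusted p = 0.158 with an estimated correlation), by 0.31, 0.46 and 0.39 within replicate numbers. Of 33 genes of the extracellular matrix, 4 rose and 2 fell, and 16 passed when adjusted over the list alone. Matrix genes together shifted upward (camera adjusted p = 0.0397; adjusted p = 0.396 with an estimated correlation; 0.0859 by fry; 0.37, 0.43 and 0.16 within replicate numbers). Col6a2, a collagen VI chain, rose 2.57-fold (455 ± 18.5 to 1171 ± 87.5, adjusted p = 0.00764), while Igfbp3, which binds insulin-like growth factors, fell 3.43-fold (218 ± 34.9 to 66.2 ± 24.6, adjusted p = 0.0291). The other probe set for Igfbp3 changed by −2.25 (adjusted p = 0.295). Of 18 B and plasma cell markers, 4 rose and 0 fell, 4 passing when adjusted over the list alone. B cell markers together shifted upward (camera adjusted p = 0.00536; adjusted p = 0.366 with an estimated correlation; 0.176 by fry; 0.73, 0.61 and 0.65 within replicate numbers), led by Jchain, the joining chain of secreted antibodies (160.3 ± 11 to 1419 ± 381, 8.66-fold, adjusted p = 0.0261). Of 22 cytokine and receptor genes, 2 rose and 0 fell, with 2 passing when adjusted over the list alone. Cytokine genes together shifted upward (camera adjusted p = 0.0231; adjusted p = 0.184 with an estimated correlation; 0.43, 0.33 and 0.62 within replicate numbers). The risers were Il1rn, the interleukin 1 receptor antagonist (at least 2.46-fold, adjusted p = 0.044), and Csf2ra, a receptor chain for GM-CSF (2.49-fold, adjusted p = 0.0464). The cytokine list lost its shift without OVA replicate 1 (adjusted p = 0.0776), and the matrix list without saline replicate 1 and OVA replicate 2 (up to 0.165). Tpm2 and Col6a2 passed with each array left out. The other genes named here lost their calls without saline replicates 1 and 2, and without OVA replicates 1 and 2, with adjusted p up to 0.0678 for Acta2, 0.0958 for Igfbp3, 0.0949 for Jchain, 0.123 for Il1rn and 0.147 for Csf2ra. Il1rn is not testable without an OVA array.

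**Figure D2:**
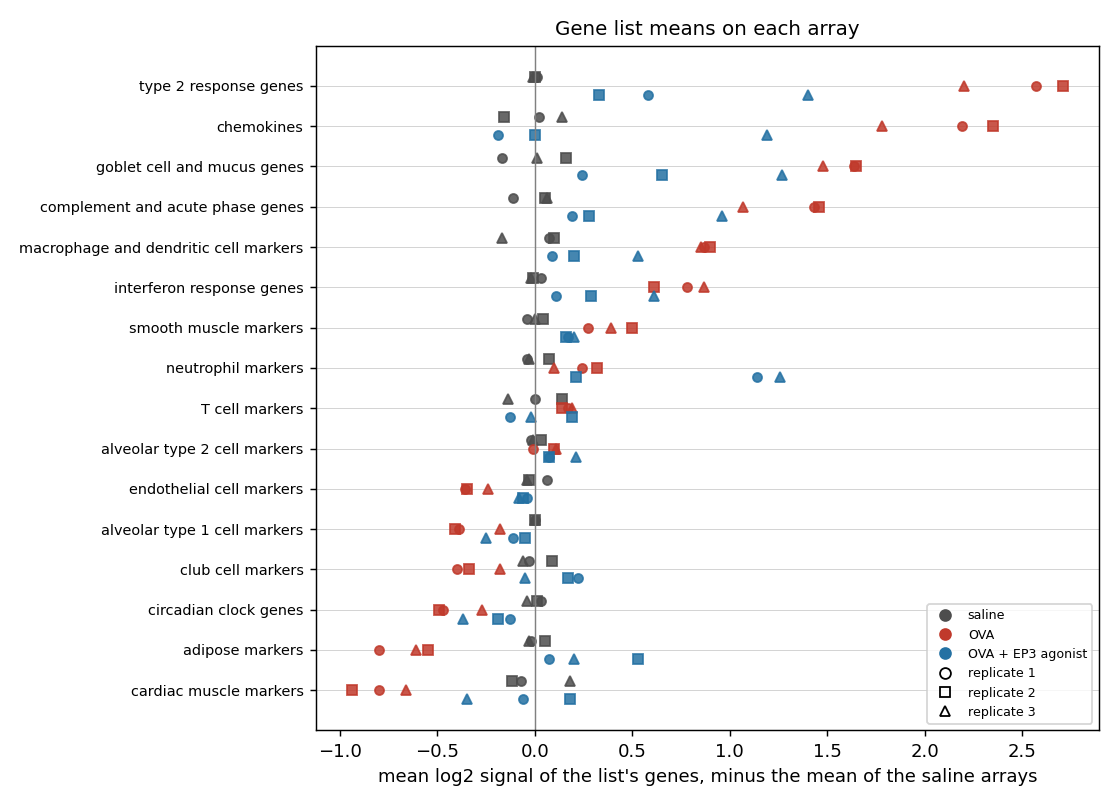
Mean log2 intensity of 16 gene lists on each of the 9 arrays, minus the mean of the saline arrays (saline grey, OVA red, agonist blue; circle, square and triangle for replicates 1, 2 and 3). For the type 2 list the OVA arrays stand at 2.57, 2.71 and 2.2 and the agonist arrays at 0.58, 0.33 and 1.4.

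Markers of heart muscle, which reaches into the lung along the pulmonary veins, were lower in OVA lung: 6 of 13 fell and 0 rose, with 10 passing when adjusted over the list alone. Mb, myoglobin, fell from 126 ± 8.7 to 37.3 ± 13.1 (47.9, 22.6 and 41.2 on the OVA arrays, near or below the detection limit; log2 change −1.82, −1.46 with values held at the limit; adjusted p = 0.0308), Tnnc1, a cardiac troponin, 2.8-fold (135 ± 2.84 to 48.8 ± 10.3, adjusted p = 0.0296), and Myh6, the atrial myosin heavy chain, 1.9-fold (342 ± 39.2 to 180.5 ± 25.2, adjusted p = 0.02). The list shifted downward (camera adjusted p = 0.000166; adjusted p = 0.165 with an estimated correlation), by −0.73, −0.82 and −0.85 within replicate numbers. Adipose markers fell in 3 of 7 cases, 4 when adjusted over the list alone, with no list call (camera adjusted p = 0.0538; −0.78, −0.6 and −0.58 within replicate numbers). Among them Car3, a carbonic anhydrase of fat, fell 2.7-fold (220.3 ± 39.9 to 81.4 ± 12.4, adjusted p = 0.0158). Red cell markers fell in 3 of 8 cases, 4 when adjusted over the list alone (camera adjusted p = 0.0538), such as Alas2, which starts heme synthesis (1.99-fold, adjusted p = 0.0278; list, −0.46, −0.43 and −0.29 within replicate numbers). Mb, Tnnc1, Myh6 and Alas2 lost their calls without any 1 saline array and without OVA replicates 1 and 2 (adjusted p up to 0.0909, 0.1, 0.0772 and 0.0858). Mb also lost it without OVA replicate 3, and Car3 without saline replicates 1 and 2 and OVA replicate 1 (up to 0.0655).

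Endothelial markers fell in 12 of 24 cases and rose in 1, with 19 passing when adjusted over the list alone. Icam2, an adhesion molecule of resting endothelium, fell 1.52-fold (490.3 ± 23.8 to 323 ± 26, adjusted p = 0.015) and Sox17, an endothelial transcription factor, 1.59-fold (438 ± 59.1 to 273.5 ± 6.8, adjusted p = 0.029). Vcam1, an adhesion molecule of activated endothelium, rose 1.67-fold (275.5 ± 27.2 to 458 ± 19, adjusted p = 0.0245). Other probe sets changed by −0.46 for Sox17 (adjusted p = 0.43) and by 1.12 and 0.42 for Vcam1 (adjusted p = 0.00854 and 0.191). Endothelial markers together shifted downward (camera adjusted p = 0.000233; adjusted p = 0.158 with an estimated correlation), by −0.42, −0.33 and −0.2 within replicate numbers. Alveolar type 1 cell markers fell in 5 of 8 cases, 6 when adjusted over the list alone, Vegfa by 1.63-fold (1432 ± 231 to 878.5 ± 147, adjusted p = 0.0369) and Ager by 1.35-fold (4695 ± 156 to 3485 ± 63.5, adjusted p = 0.0233). Type 1 cell markers together shifted downward (camera adjusted p = 0.0329; adjusted p = 0.263 with an estimated correlation; −0.39, −0.41 and −0.18 within replicate numbers). Of 14 circadian clock genes, 3 fell and 0 rose, 7 passing when adjusted over the list alone. Clock genes together shifted downward (camera adjusted p = 0.0305; adjusted p = 0.206 with an estimated correlation; −0.51, −0.5 and −0.23 within replicate numbers). The falls were of Nr1d1, a repressor of the clock, by 2.47-fold (721 ± 75.7 to 293 ± 49.6, adjusted p = 0.00974), Dbp by 1.9-fold (adjusted p = 0.0335) and Tef by 1.82-fold (adjusted p = 0.0379), both clock-driven transcription factors. The titles of the saline arrays carry no time, so it is not known whether the groups were sampled at equal times. The type 1 and clock lists lost their shifts without OVA replicate 2 (adjusted p = 0.0702 and 0.061). Nr1d1 passed with each array left out. The other genes named here lost their calls without OVA replicates 1 and 2 and without saline replicates 1 and 3, with adjusted p up to 0.0631 for Icam2, 0.0933 for Sox17, 0.0895 for Vcam1, 0.124 for Vegfa, 0.0877 for Ager, 0.11 for Dbp and 0.127 for Tef.

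Most of the 10 largest falls of single genes lay outside these lists. Pon1, a paraoxonase carried in plasma, fell from 419 ± 55.9 to 49.8 ± 40 (53.5, 8 and 87.9 on the OVA arrays; log2 change −3.63 ± 0.82, −2.81 with values held at the detection limit; adjusted p = 0.0355), and Aanat, the enzyme that limits melatonin synthesis, at least 5.02-fold (227.5 ± 42.6 to 33.4 ± 4.7, adjusted p = 0.0181). Pax4 and Six4, developmental transcription factors, fell at least 1.77-fold (79.6 ± 10.5 to −74.5 ± 35.8, adjusted p = 9.94e-06) and at least 1.89-fold (85.3 ± 13.6 to −7.79 ± 11.9, adjusted p = 0.00203), both from levels little above the detection limit. Rises outside the lists included Fbp1, an enzyme of glucose synthesis (−22.5 ± 6.31 to 381 ± 70.2, at least 8.42-fold, adjusted p = 3.57e-07), and Igf1, insulin-like growth factor 1 (0.793 ± 5.66 to 139 ± 47.4, at least 2.96-fold, adjusted p = 0.0227). Other probe sets for Six4 changed by −0.36 (adjusted p = 0.0697) and −0.14 (adjusted p = 0.52), and the other for Igf1 by 0.07 (adjusted p = 0.88). Pax4 and Six4 passed with each array left out, with all OVA arrays below the floor. Fbp1 passed without each saline and each agonist array and, like Igf1, is not testable without an OVA array. Pon1 lost its call without any 1 saline array, OVA replicate 1 or agonist replicate 2 (up to 0.102), Aanat, not testable without a saline array, without OVA replicates 1 and 2 (0.0688) and Igf1 without any 1 saline array (0.0717).

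Camera did not call the other lists between OVA and saline. Fry called 5 of these: ciliated (adjusted p = 0.0056) and club cell markers (0.0185), prostaglandin and leukotriene genes (0.0185), adipose markers (0.00683) and red cell markers (0.00451). Club cell markers fell in 5 of 11 cases and rose in 1, 8 when adjusted over the list alone (camera adjusted p = 0.0701). Besides Cyp2f2, Gsta3, a glutathione transferase, fell 1.58-fold (adjusted p = 0.0313) and Gsto1, of the same enzyme class, rose 1.8-fold (984 ± 92.8 to 1769 ± 94.9, adjusted p = 0.0135). Alveolar type 2 cell markers rose in 2 and fell in 1 of 10 cases, 4 when adjusted over the list alone (camera adjusted p = 0.501). Fabp5, a fatty acid binding protein, rose 1.67-fold (adjusted p = 0.0226), while Sftpb, surfactant protein B, fell 1.41-fold (adjusted p = 0.0371). Neutrophil markers numbered 1 riser of 12, Lcn2, lipocalin 2, also secreted by airway epithelium (539 ± 38.6 to 2518 ± 479, 4.62-fold, adjusted p = 0.0212; other probe set 0.39, adjusted p = 0.183), and 1 when adjusted over the list alone (camera adjusted p = 0.501; list mean 0.22, median −0.06). Stress and glucocorticoid responsive genes rose in 2 of 20 cases, Lcn2 and Gclc, of glutathione synthesis (1.99-fold, adjusted p = 0.0133), the same number when adjusted over the list alone (camera adjusted p = 0.685, upward, with a mean of −0.05 and a median of −0.13). In the mast cell list 1 of 7 fell, Gata2, which endothelium also expresses (1.72-fold, adjusted p = 0.0382), with 4 passing when adjusted over the list alone (camera adjusted p = 0.771). Among 22 immediate early genes 1 fell, Jun (1.46-fold, adjusted p = 0.0454), with 0 when adjusted over the list alone (camera adjusted p = 0.725). No tested member passed among 13 T cell markers (camera adjusted p = 0.196), 7 cytotoxic cell markers (0.898; upward, with a mean of −0.05 and a median of 0), 5 markers of ciliated cells (0.407), 7 of skeletal muscle (0.598) and 5 of thymus (0.576). With p adjusted over the list alone, 2 ciliated cell markers did. Without OVA replicates 1 and 2, Fabp5, Sftpb, Lcn2, Gclc, Gsta3, Gata2, Jun and Cyp2f2 lost their calls (highest adjusted p 0.0768, 0.117, 0.0797, 0.0631, 0.11, 0.127, 0.121 and 0.0534), most of them also without a saline array, and Gsto1 without OVA replicate 1 (0.0631).

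Of the receptors of prostaglandin E2, Ptger3, which encodes EP3, read below the detection limit on all 9 arrays with both of its probe sets (−7.26 ± 2.29 and 0.157 ± 3 in OVA lung), as did Ptger1 (−153.8 ± 73.1 in OVA lung), and neither was tested. Ptger2 averaged 48.1 ± 5.67 in saline, 57.8 ± 6.05 in OVA and 54.4 ± 4.55 in agonist lung (adjusted p = 0.2 for OVA against saline and 0.716 for agonist against OVA). Ptger4 averaged 11.5 ± 2, 62.9 ± 26 and 8.80 ± 6.62, without a test, since too few arrays exceeded the filter. Of 16 tested prostaglandin and leukotriene genes, 2 rose and 2 fell, 4 when adjusted over the list alone (camera adjusted p = 0.196). Besides Alox15, Pla2g4a, the phospholipase that releases arachidonic acid, rose 1.61-fold (82.3 ± 6.49 to 132 ± 8.61, adjusted p = 0.0109), and passed with each array left out. Hpgd, the enzyme that inactivates prostaglandins, fell 1.58-fold (1394 ± 102 to 887 ± 156, adjusted p = 0.0348), and Ptgfr, the receptor of prostaglandin F, 1.64-fold (92.5 ± 7.17 to 57.3 ± 11.7, adjusted p = 0.0427; other probe set −0.03, adjusted p = 0.96). Hpgd and Ptgfr lost their calls without any 1 saline array and without OVA replicates 1 and 2 (up to 0.119 and 0.121).

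The change from OVA to agonist lung asks what the EP3 agonist altered in challenged mice. With the agonist 6 of 21 type 2 response genes fell, as did 3 of 17 chemokines, 6 of 28 macrophage markers and 2 of 30 interferon genes, while 4 of 7 markers of fat, 1 of 13 of heart muscle, 3 of 24 of endothelium and 3 of 11 of club cells rose. Camera called a shift of each of these lists, 15 of 29 in all, and 0 with an estimated correlation (adjusted p between 0.213 and 0.28 for these lists). Ccl17 fell from 579.6 ± 132 to −57.0 ± 30.1, at least 12.7-fold (adjusted p = 4.44e-07), Fbp1 from 381 ± 70.2 to −15.03 ± 14.5, at least 8.42-fold (adjusted p = 3.57e-07), and Mmp12 from 2046 ± 330 to 311 ± 133, 6.91-fold (log2 change −2.79 ± 0.35, adjusted p = 0.0225). The other probe set for Mmp12 changed by −3.76 (adjusted p = 0.0565). Car3 rose 3.72-fold (81.4 ± 12.4 to 307 ± 77.2, adjusted p = 0.0158) and Cyp2f2 1.89-fold (1834 ± 215 to 3477 ± 467, adjusted p = 0.0356).

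Between agonist and OVA lung, 218 of 7920 probe sets (185 genes) passed limma's test, 99 higher and 119 lower, 80 by at least 2-fold, and 1919 had an unadjusted p under 0.05. The groups did not overlap in 29.8% of the tested probe sets, against 10% by chance. Equal array medians gave 76 higher and 132 lower, a higher share of 36.5% against 45.4%. The count moved with every array left out: 24, 26 and 36 without saline replicates 1, 2 and 3, 7, 10 and 128 without OVA replicates 1, 2 and 3, and 18, 31 and 526 without agonist replicates 1, 2 and 3. It was 14 with the replicate number as a block and 18 with only the 6 arrays compared. Of 50 calls of named probe sets, 4 passed with each of the 9 arrays left out (Adipor1, Pax4, Six4 and Slc25a25), 5 passed in 6 such settings but are not testable without an OVA array, and 3 (Fabp5, Hspa1a and Myl9) passed in no setting. In each of the 4, all arrays of a group lay below the floor: OVA for Pax4 and Six4, agonist for Adipor1 and Slc25a25. Their p-values leave that group's spread out. Adipor1 read 51.6, 37.3 and 35.2 on the OVA arrays, near or below the detection limit, and −35.8, −12 and −34.8 on the agonist arrays. With the replicate block 10 of the 50 passed: Adipor1, Alox15, Car3, Ccl17, Chaf1a, Fbp1, Pax4, Six4, Slc25a25 and Usp5. Without OVA replicates 1, 2 and 3, 38, 38 and 20 of 42 were lost, without saline replicates 1, 2 and 3, 39, 37 and 36 of 50, and without agonist replicates 1, 2 and 3, 38, 38 and 3 of 50.

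Of 21 type 2 response genes, 6 fell with the agonist and 0 rose, with 12 passing when adjusted over the list alone. Besides Ccl17 and Mmp12, Alox15 fell at least 4.1-fold (197 ± 84.8 to −16.1 ± 16.5, adjusted p = 7.98e-05) and Ccl11 from 493 ± 201 to 26.2 ± 35.1 (9.7, 2.4 and 66.5 on agonist replicates 1, 2 and 3; log2 change −5.19 ± 0.98, −3.17 with values held at the detection limit; adjusted p = 0.0444). Type 2 response genes together shifted downward (camera adjusted p = 1.29e-08; adjusted p = 0.213 with an estimated correlation), by −2, −2.38 and −0.8 within replicate numbers 1, 2 and 3. Of 17 chemokines, 3 fell (Ccl17, Ccl11 and Ccl2) and 0 rose, 9 when adjusted over the list alone. Chemokines together shifted downward (camera adjusted p = 3.65e-05; adjusted p = 0.213 with an estimated correlation; −2.39, −2.35 and −0.6 within replicate numbers). Ccl2 fell at least 2.39-fold (117 ± 54.5 to 6.61 ± 12.6, adjusted p = 0.0381). Goblet cell genes shifted downward as a list (camera adjusted p = 0.000812; adjusted p = 0.241 with an estimated correlation; −1.4, −1 and −0.21 within replicate numbers). Of its 14 members 0 passed, as did 0 when adjusted over the list alone. Clca1 averaged 2032 ± 2750 in agonist lung (257, 645 and 5194 on replicates 1, 2 and 3; log2 change −2.69, adjusted p = 0.137). Without agonist replicate 3 the change of Clca1 was −3.91 (adjusted p = 0.00307). That array was the one nearest OVA lung for Clca1, so leaving it out favours a call and gives no support. Ccl17, Fbp1 and Alox15 passed without each saline and each agonist array and, like Ccl2, are not testable without an OVA array. Ccl11 and Ccl2 kept their calls only without agonist replicate 3 (adjusted p up to 0.157 and 0.0896), and Mmp12 lost it without saline replicate 1, OVA replicates 1 and 2, and agonist replicates 1 and 2 (up to 0.112).

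Macrophage and dendritic cell markers fell in 6 of 28 cases and rose in 1, with 18 passing when adjusted over the list alone. C1qb fell 3.1-fold (714 ± 30.9 to 244 ± 107, adjusted p = 0.0363), C1qa 2.38-fold (813.5 ± 45.1 to 355 ± 124, adjusted p = 0.0421), and H2-Ab1, a chain of the class II antigen-presenting molecule, 2.27-fold (1724 ± 18.2 to 772 ± 158, adjusted p = 0.0421). Another probe set for C1qb changed by 0.04 (adjusted p = 0.933). Macrophage markers together shifted downward (camera adjusted p = 2.04e-08; adjusted p = 0.241 with an estimated correlation), by −0.79, −0.7 and −0.33 within replicate numbers. Complement genes fell in 3 of 17 cases, 9 when adjusted over the list alone. Complement genes as a list shifted downward (camera adjusted p = 0.000565; adjusted p = 0.245 with an estimated correlation; −1.24, −1.18 and −0.11 within replicate numbers). Interferon response genes fell in 2 of 30 cases, 4 when adjusted over the list alone. Interferon response genes as a list shifted downward (camera adjusted p = 0.000116; adjusted p = 0.28 with an estimated correlation; 0.0551 by fry; −0.67, −0.32 and −0.26). The falls were of Ifi30, a thiol reductase of antigen processing, by 2.01-fold (483 ± 94.1 to 241 ± 52.9, adjusted p = 0.0444), and Psmb8, of the immunoproteasome, by 1.45-fold (932 ± 42.4 to 642 ± 63.2, adjusted p = 0.0421). Cell cycle genes fell in 3 of 25 cases, 8 when adjusted over the list alone. Cell cycle genes as a list shifted downward (camera adjusted p = 0.000231; adjusted p = 0.213 with an estimated correlation; −0.64, −0.02 and −0.25). The falls were of Cks2, at least 1.87-fold (adjusted p = 0.0363), Mad2l1, 2.06-fold (adjusted p = 0.0366) and Pcna, the DNA clamp of replication, 1.45-fold (599 ± 52.3 to 412 ± 24, adjusted p = 0.0426). All of these genes lost their calls without saline replicates 1, 2 and 3 and agonist replicates 1 and 2, and without OVA replicates 1 and 2, except that Cks2 is not testable without an OVA array, with adjusted p between 0.106 for Cks2 and 0.147 for Ifi30 at the highest.

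Col6a2 fell 2.47-fold with the agonist (1171 ± 87.5 to 478 ± 84.3, adjusted p = 0.00849) and Col6a1, which forms collagen VI with it, 1.42-fold (1728 ± 32 to 1222 ± 98.4, adjusted p = 0.0368). With Mmp12 they made 3 falls among 33 matrix genes, 10 when adjusted over the list alone. Matrix genes as a list shifted downward (camera adjusted p = 0.0093; adjusted p = 0.343 with an estimated correlation; 0.0561 by fry; −0.32, −0.41 and −0.16 within replicate numbers). Smooth muscle genes gave 1 fall of 11, Myl9, a myosin light chain (1.43-fold, adjusted p = 0.0446), and 4 when adjusted over the list alone. Smooth muscle genes as a list shifted downward (camera adjusted p = 0.00361; adjusted p = 0.241 with an estimated correlation; −0.11, −0.33 and −0.18). Among 18 B and plasma cell markers no gene passed, 2 when adjusted over the list alone. B cell markers as a list shifted downward (camera adjusted p = 0.00514; adjusted p = 0.343 with an estimated correlation; 0.165 by fry; −1.23, −0.61 and −0.07). Jchain averaged 357 ± 359 with the agonist (adjusted p = 0.0705; 0.00164 without agonist replicate 3). Agonist replicate 3 read 770.7 and lay nearest OVA lung, so leaving it out favours a call and gives no support. Heat shock genes Hspa1a and Dnajb1, of the stress list (2 of 20 fell, 6 when adjusted over the list alone, camera adjusted p = 0.165), fell 2.84-fold (298 ± 43.9 to 107.5 ± 34.5, adjusted p = 0.0455) and 1.86-fold (223 ± 10.1 to 121 ± 22.3, adjusted p = 0.0436). Among the 10 largest falls were also Usp5, a deubiquitinase (at least 2.44-fold, adjusted p = 0.00849), Chaf1a, a histone chaperone (at least 1.76-fold, adjusted p = 4.19e-05), and Slc25a25, a mitochondrial carrier (77.3 ± 13.2 to −25.4 ± 28.4, at least 1.71-fold, adjusted p = 6.55e-05). Slc25a25 passed with each array left out, with all agonist arrays below the floor. Usp5 and Chaf1a passed without each saline and each agonist array and are not testable without an OVA array. Col6a2 lost its call without OVA replicates 1 and 2 (0.0866), and Col6a1 and Dnajb1 lost theirs without any array but agonist replicate 3 (0.131 and 0.145). Myl9 and Hspa1a lost theirs whichever array was left out (0.134 and 0.145), the matrix list without OVA replicate 2 (0.0566) and the B cell list without agonist replicate 1 (0.113).

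Adipose markers rose in 4 of 7 cases with the agonist and fell in 0, with 5 passing when adjusted over the list alone. Besides Car3, Adipoq, the fat hormone adiponectin, rose 2.16-fold (74.6 ± 6.39 to 164 ± 39.2, adjusted p = 0.0356), and Pck1, of glucose and glyceride synthesis, at least 1.24-fold (17.2 ± 6.28 to 57.4 ± 18.9, adjusted p = 0.0421). The list shifted upward (camera adjusted p = 0.000158; adjusted p = 0.213 with an estimated correlation), by 0.87, 1.08 and 0.81 within replicate numbers. In the heart muscle list 1 of 13 rose, Myh6, 1.97-fold (180.5 ± 25.2 to 356.5 ± 57.6, adjusted p = 0.0366), with 8 passing when adjusted over the list alone. The list shifted upward (camera adjusted p = 0.000158; adjusted p = 0.213 with an estimated correlation; 0.73, 1.12 and 0.31 within replicate numbers). Endothelial markers rose in 3 of 24 cases, 16 when adjusted over the list alone. Endothelial markers as a list shifted upward (camera adjusted p = 0.000683; adjusted p = 0.213 with an estimated correlation; 0.32, 0.3 and 0.16). The rises were of Eng, endoglin, 1.51-fold (2830 ± 229 to 4267 ± 201, adjusted p = 0.0363), Tek, the angiopoietin receptor, 1.61-fold (adjusted p = 0.0475), and Cdh5, the cadherin of endothelial junctions, 1.36-fold (adjusted p = 0.0475). Club cell markers rose in 3 of 11 cases, 7 when adjusted over the list alone. Club cell markers as a list shifted upward (camera adjusted p = 0.00514; adjusted p = 0.241 with an estimated correlation; 0.62, 0.51 and 0.14). The rises were of Cyp2f2, of Gsta3, 1.7-fold (adjusted p = 0.0424) and Cyp4b1, another P450, 1.59-fold (adjusted p = 0.0455). Red cell markers rose in 1 of 8 cases, Hba-a1, an alpha globin, 1.52-fold (adjusted p = 0.0411), 3 when adjusted over the list alone. Red cell markers as a list shifted upward (camera adjusted p = 0.012; adjusted p = 0.213 with an estimated correlation; 0.4, 0.53 and 0.27), a shift that was lost without OVA replicate 3 (0.0535). Car3 lost its call without OVA replicates 1 and 2 (0.1). The other genes named here lost theirs without OVA replicates 1 and 2 and without saline replicates 1 and 2, most of them also without agonist replicates 1 and 2, with adjusted p up to 0.171 for Tek.

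Rises outside these lists included Cyp2e1, a P450 that oxidizes small molecules (119 ± 4.45 to 373 ± 98, 3.06-fold, adjusted p = 0.0356), Prss8, a membrane-bound protease of epithelia (111 ± 25 to 306 ± 49.4, 2.79-fold, adjusted p = 0.0381), and Acot1, an acyl-CoA thioesterase (59.04 ± 5.5 to 144 ± 36.4, 2.4-fold, adjusted p = 0.0381). Pax4 rose at least 2.01-fold (−74.5 ± 35.8 to 91.3 ± 18.2, adjusted p = 7.38e-06), and Six4 rose from −7.79 ± 11.9 to 65.5 ± 37 (105.5, 32.7 and 58.4 on the agonist arrays; log2 change 0.54 with values held at the detection limit; adjusted p = 0.00306). Both passed with each array left out. Their OVA arrays all lay below the floor, so the p-values leave that group's spread out. Other probe sets for Six4 changed by 0.31 and 0.34 (adjusted p = 0.128 and 0.163). Hpgd rose 1.89-fold (887 ± 156 to 1670 ± 205, adjusted p = 0.0363) in a list of 16 prostaglandin and leukotriene genes with 1 rise and 1 fall, 6 when adjusted over the list alone (camera adjusted p = 0.134). Nr1d1 rose 1.95-fold (293 ± 49.6 to 572 ± 90.3, adjusted p = 0.0397) and Bhlhe40, another repressor of the clock, fell 1.75-fold (591.5 ± 53.2 to 343 ± 73.7, adjusted p = 0.0491), among 14 clock genes (4 when adjusted over the list alone, camera adjusted p = 0.182). Cyp2e1, Prss8, Hpgd, Nr1d1, Acot1 and Bhlhe40 lost their calls without saline replicates 1 and 2, OVA replicates 1 and 2 and agonist replicates 1 and 2 (up to 0.131, 0.131, 0.131, 0.145, 0.142 and 0.145). Neutrophil markers did not pass (0 of 12, 3 when adjusted over the list alone, camera adjusted p = 0.11). S100a9, a calcium-binding protein of neutrophils, read 1542, 128 and 1180.5 on agonist replicates 1, 2 and 3 against a mean of 117 ± 30.2 in OVA lung (log2 change 2.43, adjusted p = 0.136). Without agonist replicate 2 the change of S100a9 was 3.56 (adjusted p = 0.00148). That array was the one nearest OVA lung for S100a9, so leaving it out favours a call and gives no support.

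Camera did not call the other lists between agonist and OVA lung. Fry called 5 of these: alveolar type 1 cell markers (adjusted p = 0.0257), neutrophil markers (0.048), prostaglandin and leukotriene genes (0.0386), ciliated cell markers (0.0406) and thymus markers (0.0441). Alveolar type 1 cell markers rose in 1 of 8 cases, 6 when adjusted over the list alone (camera adjusted p = 0.11), namely Cav1, the scaffold of caveolae (1.37-fold, adjusted p = 0.0444; other probe set 0.33, adjusted p = 0.215). Alveolar type 2 cell markers fell in 1 of 10 cases, Fabp5 (1.62-fold, adjusted p = 0.0446), 3 when adjusted over the list alone (0.586). No member passed among cytokine genes (0.148), T cell markers (0.183), cytotoxic cell markers (0.586), mast cell markers (0.713), ciliated cell markers (0.713), immediate early genes (0.467), and markers of skeletal muscle (0.782) and thymus (0.165). With p adjusted over the list alone, 2 thymus markers, 1 T cell marker and 1 immediate early gene did. Cav1 passed only without agonist replicate 3 (adjusted p up to 0.157) and Fabp5 in no setting with an array left out (0.0531 to 0.145).

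**Figure D3:**
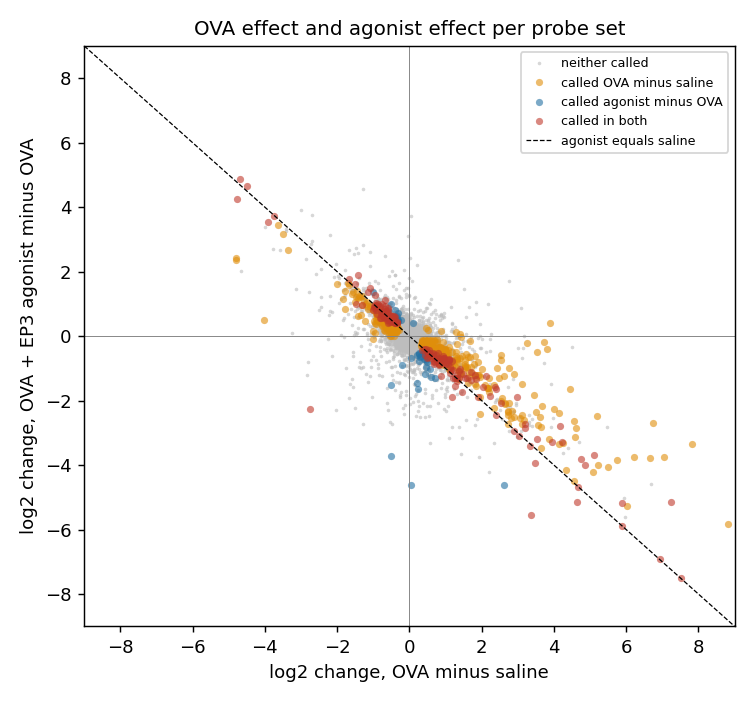
Log2 change from saline to OVA (horizontal) against log2 change from OVA to agonist (vertical) for the 7920 tested probe sets, each a point coloured by the comparisons it passed, with a dashed line where agonist equals saline. Of the 402 probe sets higher in OVA lung 94 were lower with the agonist, and of the 350 lower ones 87 were higher.

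Of all tested probe sets 94 were called higher in OVA and lower with the agonist (6.04 for independent lists), 87 were called the reverse (4.38), and 1 was called in the same direction by both. Both comparisons share the OVA arrays, which by itself makes their changes run opposite, and the numbers for independent lists do not allow for that. Across probe sets the changes correlated with r = −0.773, against a mean of −0.499 and a lowest of −0.564 in 100 simulations of unchanged groups. Their covariance was −0.377, of which the shared arrays account for −0.0832 and −0.293 remains. The 3 OVA arrays are too few to split into 2 sets of 2, so part of the excess of the correlation and of the shared calls may come from shared arrays, a part that the remaining covariance leaves out. With the compared OVA array left out of the picking, probe sets that OVA raised changed by −0.945 with the agonist, the mean of medians of −1.279, −1.04 and −0.515 against OVA replicates 1, 2 and 3. Of these 93.6% moved downward, and the OVA effect was 1.383. Those that OVA lowered changed by 0.478 (0.587, 0.512 and 0.336), with 83.2% upward and an OVA effect of −0.601. Among all 20 labelings of the challenged arrays the exact permutation p was 0.2 (two-sided) for the raised and 0.55 for the lowered probe sets. The smallest p that 20 labelings can give is 0.05, so this test cannot pass the threshold. The observed p also lay above that minimum. Other labelings gave changes larger in size, up to 2.154 for the raised and 5.155 for the lowered probe sets. The 2.154 is opposite in sign to the observed change, and the one-sided permutation p was 0.1 for the raised and 0.35 for the lowered probe sets. Probe sets were picked anew for each labeling, so the labelings compare medians of unlike sets of unlike size. For that reason too the permutation decides nothing about the agonist effect. The agonist effects depend on the arrays and on the probe sets, which were picked anew in each setting. Between OVA and saline 752 probe sets were called with all 9 arrays. The count was 150, 138 and 126 without saline replicates 1, 2 and 3, and 50 with the replicate block. The values below are therefore not of the same probe sets, and the OVA effect on each set is not given. On the raised probe sets the effect was −4.872, −4.395 and −2.746 without saline replicates 1, 2 and 3, −1.489, −1.529 and −1.497 without OVA replicates 1, 2 and 3, −1.64 without agonist replicate 1 and −5.173 with the replicate block. On the lowered ones it was 3.325, 4.437 and 2.554 without saline replicates 1, 2 and 3, 0.263 without OVA replicate 2 and 3.178 with the replicate block. The remaining covariance was −0.192 and −0.212 without OVA replicates 1 and 2 and −0.358 without agonist replicate 3.

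The change from saline to agonist lung asks how far treated lung still lay from unchallenged lung. Was, the actin regulator of blood cells that is missing in Wiskott-Aldrich syndrome, averaged 41.6 ± 5.34 in saline, 132 ± 5.67 in OVA and 119 ± 18.2 in agonist lung (47.8, 38.6 and 38.5 on the saline arrays; log2 change from saline 1.51 ± 0.14, 1.37 with values held at the detection limit; adjusted p = 0.0101). Tpm2 stood 2.62-fold above saline (89.6 ± 8.9 to 235 ± 20.1, adjusted p = 0.0496) and Cog5, of the Golgi, 1.63-fold (68.9 ± 3.16 to 112 ± 6.43, adjusted p = 0.0496). Aanat was at least 5.02-fold lower (227.5 ± 42.6 to 7.68 ± 4.72, adjusted p = 0.0101), Slc25a25 at least 1.67-fold (77.2 ± 24.2 to −25.4 ± 28.4, adjusted p = 0.000243) and Adipor1, an adiponectin receptor, at least 1.3-fold (58 ± 1.53 to −27.5 ± 13.5, adjusted p = 2.39e-05). These 6 probe sets were all that passed limma's test, with 611 at an unadjusted p under 0.05 and 13.6% with non-overlapping groups against 10% by chance. Was, Slc25a25 and Adipor1 passed with each array left out. For Slc25a25 and Adipor1 all agonist arrays lay below the floor, which leaves that group's spread out of their p-values. Aanat passed without each OVA and each agonist array and is not testable without a saline array. Tpm2 kept its call only without OVA replicates 1 and 3 (up to 0.16) and Cog5 in no such setting (0.0874 to 0.201). Without agonist replicate 2 the count was 16, and with the replicate number as a block it was 2 (Slc25a25 and Adipor1).

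As lists, macrophage markers (camera adjusted p = 1.96e-05), interferon response genes (1.96e-05), type 2 response genes (2.53e-05), neutrophil markers (0.000146), complement genes (0.00263), goblet cell genes (0.00809), adipose markers (0.0114) and alveolar type 2 markers (0.0427) stood higher in agonist than in saline lung, and clock genes lower (0.0344). Each had an adjusted p = 0.424 with an estimated correlation, which called 0 of 29 lists (1 at an unadjusted p under 0.05), as did fry (5 at an unadjusted p under 0.05). None of their members passed on its own, and adjusted over the list alone 2 goblet cell and 2 adipose genes did. Clca1 averaged 57.4 ± 8.4 in saline and 2032 ± 2750 in agonist lung (adjusted p = 0.366), S100a9 115 ± 14.8 and 950.1 ± 734 (adjusted p = 0.535), and S100a8, its partner in neutrophils, 325 ± 72.5 and 1532 ± 1090 (adjusted p = 0.62). Without agonist replicate 2, S100a9 (adjusted p = 0.00292) and S100a8 (adjusted p = 0.0131) passed. On that array both read near saline lung (128.1 and 287.3), so leaving it out favours a call and gives no support. On agonist replicates 1, 2 and 3 the type 2 list stood at 0.58, 0.33 and 1.4 above saline, the goblet list at 0.24, 0.65 and 1.27 and the neutrophil list at 1.14, 0.21 and 1.26. The macrophage, interferon, type 2 and neutrophil lists passed camera with each array left out. Without saline replicate 1 the count of lists was 4, as complement (0.0599), goblet (0.0599), adipose, type 2 cell and clock lists lost their calls. Adipose markers also lost it without agonist replicate 2 (up to 0.0617). Type 2 cell markers lost it without saline replicate 2 and agonist replicates 1 and 3 (up to 0.266), and clock genes without saline replicate 3 and agonist replicates 2 and 3 (up to 0.266).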

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

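The alternatives below were chosen before the results were seen, and only the check of the replicate numbers and the sets of named genes per left-out array were chosen afterwards. For OVA against saline, 752 probe sets became 50 with the replicate block, 1511 at an adjusted p under 0.1 and 241 with at least 2-fold, and 9 of 12 alternatives left the count about the same. For agonist against OVA, 8 of 12 moved 218: 361 with a floor at the 40th percentile, 445 with a filter at the 60th, 453 with an intensity trend and a robust prior, 498 with array weights, 18 with only the 6 arrays compared, 14 with the replicate block, 831 at an adjusted p under 0.1 and 80 with at least 2-fold. For agonist against saline, 6 became 3 with the filter at the 60th percentile and 2 with the replicate block. Camera with an estimated correlation shifted 0 lists for OVA against saline (8 at an unadjusted p under 0.05; 18 by fry), 0 for agonist against OVA (6; 17 by fry) and 0 for agonist against saline (1), where fry also gave 0 (5). The covariance of both changes was −0.166 with the floor at the 40th percentile. The agonist effect on probe sets OVA raised was −0.493 without the filter and −5.173 with the replicate block, and on those OVA lowered 0.349 and 3.178. Each setting picked its probe sets anew, so these values are not of the same probe sets. With each array left out in turn, the counts ran from 80 to 857 for OVA against saline, 7 to 526 for agonist against OVA and 5 to 16 for agonist against saline, and the lists from 13 to 18, 14 to 16 and 4 to 10. The agonist effects, on probe sets picked anew each time, ran from −4.872 to −0.836 on raised and 0.263 to 4.437 on lowered probe sets. The covariance ran from −0.358 to −0.192. The replicate block and the 6 arrays leave 4 residual degrees of freedom and a left-out array 5, against 6. For OVA against saline, the 6 arrays gave 634 probe sets and the replicate block 50, a difference that the degrees of freedom alone do not account for. The fit of 6 arrays also leaves the third group out of the spread, so these 2 fits differ by more than the block. The same settings gave 18 and 14 for agonist against OVA, and 4 and 2 for agonist against saline. For these the degrees of freedom stay open. The cause was not tested. Of 139 calls of named genes, 2535 comparisons with alternatives kept 1634, lost 901 and reversed 0. The replicate block alone kept 17 of 83, 10 of 50 and 2 of 6 of these calls, and lost 66, 40 and 4. Deviations from the group means correlated between −0.139 and 0.169 for the same replicate number and between −0.154 and 0.149 for different numbers, so pairing, as in the replicate block (50, 14 and 2 probe sets), removes little spread. Between saline and OVA the same numbers correlated at 0.169, 0.112 and 0.035, and the bioD and bioC spike-in levels follow the numbers, so that a shared hybridization stays open.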

Other observations

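The gene lists in the first 2 paragraphs and the tests of all patterns below were chosen after the results were seen, and only the splits of the arrays in the last paragraph were chosen before. Lysosomal genes rose in OVA lung, 11 of 24, among them Ctsz (261 to 592, adjusted p = 0.00912) and Ctss (1254 to 2816, adjusted p = 0.0185), both cathepsins of antigen-presenting cells (list, camera adjusted p = 4.55e-06; adjusted p = 0.0944 with an estimated correlation). Of 10 genes of MHC class II, 5 rose in OVA lung (camera adjusted p = 9.38e-06; 0.167 with an estimated correlation) and 4 fell with the agonist (3.89e-06; 0.141). H2-Aa, which presents antigen to helper T cells, went from 1558 to 3269 (adjusted p = 0.0109) and fell to 1796 with the agonist (adjusted p = 0.0366). Of these lists 4 lysosomal and 6 class II genes also stand in the lists above. Gatm, of creatine synthesis from arginine, rose from 46 to 347 and fell to 54 with the agonist (adjusted p = 0.0239 and 0.0421), within 10 arginine and polyamine genes of which 3 rose (camera adjusted p = 0.000126; 0.117 with an estimated correlation). Secreted proteins of the OVA lung picked after their values were seen include Chia1, an acidic chitinase (331 to 3101, adjusted p = 0.0115; 539 with the agonist, adjusted p = 0.0366), Chil3, a chitinase-like protein of macrophages (1709 to 5617, adjusted p = 0.0187; 3115 with the agonist, adjusted p = 0.1), and Pigr, which carries antibodies across epithelium (523 to 1999, adjusted p = 0.0226; 926 with the agonist, adjusted p = 0.0927). They belong to the type 2 and mucus lists above and were not tested as a set of their own.

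Enzymes of metabolism also differed. Cytochrome P450 and flavin monooxygenase genes fell in OVA lung in 6 of 9 cases (camera adjusted p = 0.000126; 0.151 with an estimated correlation) and rose with the agonist in 3 (6.22e-05; 0.129), Fmo1 averaging 1097 in OVA lung and 1582 with the agonist (adjusted p = 0.038 for OVA against saline and 0.0829 for agonist against OVA). Oxidative phosphorylation genes rose in 4 of 25 cases, such as Cox5b, of complex IV (682 to 948, adjusted p = 0.0185). Their camera adjusted p was 3.89e-05, and 0.0381 with an estimated correlation. Both were adjusted among the lists chosen afterwards only, apart from the 29 fixed lists, of which the estimated correlation called 0. The 0.0381 therefore does not show that this list stands the stricter test. Chaperones of the endoplasmic reticulum rose in 4 of 19 cases (4.14e-05; 0.137), and Manf, induced by unfolded proteins, fell from 685 to 276 with the agonist (adjusted p = 0.0363). Glycolysis (2 of 11 rose, 0.00728; 0.117), cholesterol synthesis (2 of 12, 0.000163; 0.173), proteasome (1 of 24, 1.62e-05; 0.117) and actin regulator genes of blood cells (3 of 17, 4.55e-06; 0.142) shifted upward in OVA lung by camera. Fatty acid oxidation genes (2 of 16 fell, 0.0524), heat shock genes (0 of 14, 0.517) and ribosomal protein genes (0 of 11, 0.193) did not. With the agonist camera called 12 of these 13 lists against OVA lung, all but ribosomal protein genes, with adjusted p of 0.0994 or more with an estimated correlation. Fatty acid oxidation genes were among those higher (2 of 16 rose, 0.00212; 0.129 with an estimated correlation). Between agonist and saline lung heat shock genes shifted downward (0 of 14, 0.00033; 0.384 with an estimated correlation), and lysosomal genes (0 of 24, 0.000212; 0.312), actin regulators (1 of 17, 0.000676; 0.384) and cholesterol synthesis genes (0 of 12, 0.00436; 0.384) upward.

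Agonist replicate 3 lay closer to the OVA arrays than agonist replicates 1 and 2 did. An OVA array carrying the agonist label is argued against: set alone against 2 OVA arrays, with the spread taken from the groups of 2 or 3 arrays, agonist replicate 3 differed in 20, 23 and 45 probe sets (limma adjusted p under 0.05) and the OVA array left out in 2, 4 and 6, which passes a bound of 3 times the highest narrowly, after 2 earlier forms on 634 probe sets picked for OVA, of which the first (79.8% beyond the OVA arrays) was wrongly built and the next (85.5% against 26.3%, 39.4% and 80.9% for OVA arrays left out) decided nothing. More conducting airway in the piece of lung as the whole cause is argued against by club cell markers, which differed by −0.24 (SE 0.11) from the other agonist arrays, while goblet cell genes differed by 0.82 (SE 0.3) and ciliated cell markers by 0.91 (SE 1.11), and a part stays open, since club cell markers were also lower in OVA lung. Admixture of OVA lung RNA stays open: of 8 probe sets that its median share of 0.392 should show, 2 lay below the detection limit, Ccl17 (−90.24, where 167 or more was due) and Fbp1 (−31.71, where 119 or more was due). These are fewer than the bound of 3, which was set before this count but after other results were seen. Saa3 (362.6) and Ighm (335.8 and 53.76) were seen. Against a single share stand 18 probe sets under 25% of the median share (0, 1 and 2 on the OVA arrays), a relative interquartile range of 0.723 (at most 0.573 on the OVA arrays) and Alox15 at −26.3. A weaker response in that sample may be another explanation, and no test here tells it from admixture.

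Markers of heart muscle, fat, endothelium and type 1 cells were lower in OVA lung. Dilution by RNA of infiltrating cells as the whole cause is argued against, since it lowers all lists alike and heart muscle (−0.8) and fat (−0.65) changed more than endothelium (−0.32) and type 1 cells (−0.33; permutation p = 0.0234, members taken as independent). Alveolar type 2 (0.06, SE 0.15) and smooth muscle markers (0.39, SE 0.12) were not lower. The 4 lists differed by −0.34 (SE 0.11) from 6 other resident lists together. A part stays open, since club cell (−0.31), skeletal muscle (−0.29), red cell (−0.39) and ciliated cell markers (−0.72, SE 0.53) were lower as well. Chance variation of the heart and fat tissue taken with each piece stays open. The OVA arrays stood at −0.8, −0.8 and −0.64 and the agonist arrays at −0.02, 0.31 and −0.16 (exact one-sided permutation p = 0.0119), but these lists were chosen because they were lower, so that the test restates the pattern. A dissection that differed by group could give the same values and stays open, as does an effect of the challenge on these tissues.

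Of the 50 called probe sets with the largest change, 42 had a group at or below the detection limit. Such changes may be signals of single probe sets near background and not of the transcript. Another probe set of the gene moved the same way for 10 of 19 of these calls (52.6%) and for 117 of 155 of the others (75.5%), Fisher's exact two-sided p = 0.0524. That neither excludes the explanation nor favours it enough, and it stays open for genes with a single probe set.

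The arrays of each comparison were also split in all 10 ways into 3 and 3. The real split gave the largest count in each comparison, so 1 of 10 splits reached it: 752, 218 and 6 probe sets against at most 2, 3 and 3 for OVA against saline, agonist against OVA and agonist against saline, and 15, 15 and 9 lists against at most 11, 10 and 7. These 10 splits are too few for a share under 0.05, so that a grouping by chance is neither excluded nor favoured.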
